A study of Homo sapiens with 6 samples.

How the data were processed

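RNA from 6 dishes of the glioblastoma line U251 was analysed, 3 dishes of a stable lentiviral PD-L1 line and 3 of its vector control. Per the labels' protocols, cells were harvested 12 h after passage in medium with 10% serum, and 3 µg of total RNA per dish went through poly-T selection and the NEBNext Ultra kit, which does not mark strand. Per the submitters' processing notes, the tools were CASAVA 1.8, STAR 2.5.1b and HTSeq 0.6.0 with the genome build hg19. The gene annotation, strand setting and read filters are not given in the sources used here. The authors deposited whole-number counts per Ensembl gene, with 1 column per dish and no pooling. They also deposited normalized counts on a signal scale. Each normalized value was found to equal the raw count divided by 1 factor per dish, and these factors matched median-of-ratios factors within 5.1e-05%. The raw table holds 57773 genes, 33317 of them with a read. The normalized table holds 28633 genes, and the 4684 further genes with a read each had a total of 1 read over the 6 dishes.

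Gene symbols came from a table of gene names for 51996 IDs and from GENCODE 29 for 342 more. The 5435 IDs without a symbol kept their ID. Genes with a symbol held 99.3% of the reads. GENCODE 29 is built on another genome build than the files, so it was used only for names, biotypes, GC content, transcript length and overlaps, and no coordinates are given.

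Groups and replicate numbers were taken from the sample titles. The main comparison used raw counts of all 6 dishes in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr, scaled with TMM and tested with the robust quasi-likelihood F test (glmQLFit, glmQLFTest) without covariates. Benjamini-Hochberg FDR under 0.05 counted as changed. Log2 fold changes are PD-L1 minus Vector. Their standard errors were derived from the fold change and the F statistic. CPM values are given as mean ± SD of 3 dishes after TMM scaling. The common biological coefficient of variation was 8.6%. A list of 28 gene lists (19 pathways, 5 cell types, 4 quality measures) was fixed before the data were examined. Of these, 25 lists with at least 5 tested members were tested with camera in limma 3.58.1 on log2 CPM (prior count 2, preset correlation 0.01). The lists share members, for example TAGLN and TPM1, so they are not independent. UHRF1 and PECAM1, list members, had no matching ID and were left out.

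The text names CD274, the 12 genes with the largest increase and the 12 with the largest decrease, and, of each fixed list, the 4 tested members with the smallest FDR or, where none passed, up to 2 abundant members. The top genes had to pass the FDR, have a mean of at least 5 CPM and show no overlap between groups. Near-identical copies were left out of them, which removed 2 higher genes. The table of copies was written after values were seen. All detected cell type markers could be named. Results of 3 single genes are not reported here, although the genes stayed in the fits and in the counts of their lists. Exceptions, chosen after their values were seen, are ID2 and SNAI2, the transcription factors listed beside SNAI2, and CDKN1A.

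The comparison was repeated, as fixed before the data were examined, with relative log expression, upper-quartile and the authors' size factors, DESeq2 1.42.0, limma-voom, limma-trend on log2(normalized count + 1), no low-count filter, a mean of at least 5 CPM, the replicate number as a block, leaving out each dish, an FDR of 0.01, a change of at least 1 log2 unit, glmTreat beyond 1.2-fold, an estimated correlation in camera, and fry. For DESeq2 the lists were tested with cameraPR on its gene statistics. An offset for GC content and transcript length (natural splines with 5 degrees of freedom per dish), alone, without PD-L1 dish 3 and with the block, was added after the data were seen, as was the estimated correlation in the fits that leave out 1 dish. GC content and length were known for 97.6% of tested and 98.1% of changed genes.

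The fits were tested on simulated counts with the means and library sizes of these dishes. For the comparison of PD-L1 with Vector dishes (15630 genes), edgeR recovered 83.6% of genes changed 1.5-fold, 98.5% of those changed 2-fold and 100% of those changed 4-fold, and 8.74% of its calls were false. With a simulated GC trend the false share was 14.2% without and 4.64% with the offset. That trend was linear in GC content, with no slope in PD-L1 dish 3 and no trend with length. The trends of these dishes differ from it, so both shares need not hold for them. Camera and fry each called the planted list and 0 of 20 random lists. Genes were simulated as independent, so this does not test the lists at the correlations estimated from these dishes, such as 0.77 for collagens. Tables and plots were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9. Depths ranged from 15678989 to 22270509 counts per dish.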

Results

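Poly-A RNA was sequenced from U251, an established human glioblastoma cell line. PD-L1, the protein encoded by CD274, is a cell-surface ligand of the T-cell receptor PD-1. Cells carried either a lentiviral PD-L1 construct, or its vector control, as stable lines. Each line contributed 3 dishes, harvested 12 h after passage in medium with 10% fetal bovine serum. The question was which transcripts differ between cells that overexpress PD-L1 and vector cells. Total counts per dish were 19704409, 15678989 and 19090861 for PD-L1 dishes 1 to 3. The Vector dishes held 22270509, 20952894 and 18797948. At these depths a count of 3 corresponds to a CPM (count scaled to a common library size) of 0.135 to 0.191. The dishes of a group came from 1 transduced line, so p-values measure the spread between dishes and not between independent transductions. Replicate dishes differed by more than sampling noise, with chi-square values per degree of freedom from 3.04 to 16.1 over the pairs within a group.

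CD274 (ENSG00000120217) rose from 2.41 ± 0.97 CPM in Vector dishes to 1300 ± 61.4 CPM in PD-L1 dishes (mean ± SD, n = 3 each). The raw counts were 26827, 22001 and 23046 in PD-L1 dishes 1 to 3. They were 34, 71 and 41 in the Vector dishes. The log2 fold change was 9.07 ± 0.18 (SE), with an adjusted p of 1.45e-12 in the edgeR quasi-likelihood test. An exact two-sided permutation test of the 6 CPM values gave p = 0.1, the smallest that 3 dishes against 3 allow. CD274 ranked 59 by mean CPM in the PD-L1 dishes. Gene counts do not separate transcripts of the construct from those of the endogenous gene.

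**Figure D1:**
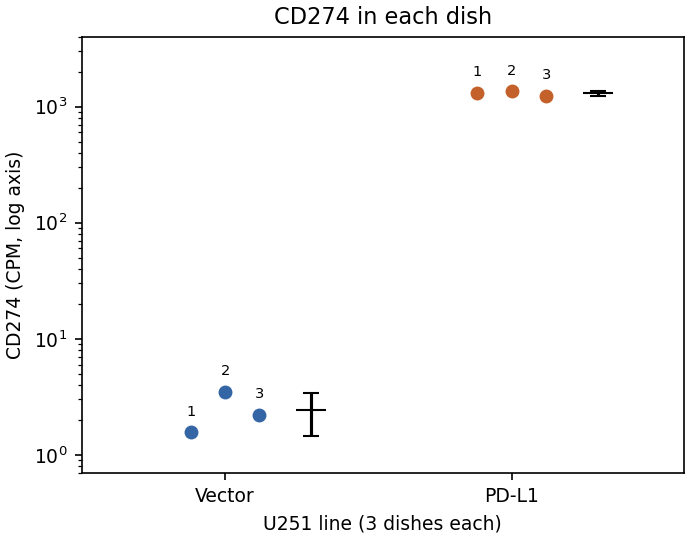
CD274 expression in CPM (log axis) for each of the 3 Vector and 3 PD-L1 dishes, numbered by dish, with the group mean and SD in black beside the points. The PD-L1 dishes lie between 1234 and 1356 CPM and the Vector dishes between 1.57 and 3.47 CPM.

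Beyond CD274, most of the genes that changed were lower in the PD-L1 dishes. Several of the 12 largest decreases were in genes of the extracellular matrix and its remodelling. FBN1, the microfibril protein fibrillin-1, was 2.60-fold lower (log2 fold change -1.38 ± 0.11). COL1A1, a chain of type I collagen, fell from 837 ± 171 to 340 ± 36.4 CPM. THBS1 (ENSG00000137801), the matricellular protein thrombospondin-1, fell from 126 ± 3.14 to 51.6 ± 1.92 CPM, with an adjusted p of 5.53e-07. The related THBS2, the small proteoglycan BGN and the membrane-bound metalloproteinase MMP14 were 2.54-fold, 2.54-fold and 2.52-fold lower. The other members of the 12 largest decreases were SSC5D, NGB (the oxygen-binding protein neuroglobin), TNS1 (the focal-adhesion protein tensin-1), MDFI, PLXNA4 and APCDD1L. Their log2 fold changes lay between -1.59 and -1.31.

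Fewer genes were higher. At a mean of at least 5 CPM, the 12 largest increases besides CD274 were smaller than the 12 largest decreases. C3, the central complement component, rose from 4.42 ± 1.17 to 9.83 ± 0.40 CPM, a log2 fold change of 1.15 ± 0.17. PURPL, a long noncoding RNA induced by p53, rose 1.74-fold and TP53INP1, another p53-inducible gene, rose 1.65-fold. ALKAL1, which encodes a ligand of ALK-family receptors, rose 1.75-fold. FOXN4, L3MBTL1, LINC00649, ATF7IP2 and GABRE rose by log2 fold changes of 0.61 to 0.70. The remaining 3 of the 12 largest increases have no symbol, among them ENSG00000188206 and ENSG00000235477 with log2 fold changes of 1.06 and 0.70. Within these 24 genes, NGB, TNS1, THBS1, L3MBTL1 and LINC00649 overlap a gene on the opposite strand in GENCODE 29. The library kit does not mark strand, so reads of such partners cannot be separated.

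Of 15818 genes tested, 1384 passed a false discovery rate (FDR) of 0.05, with 245 higher and 1139 lower in PD-L1 dishes. The lower genes made up 82.3% of these calls, against 72.8% with upper-quartile scaling and 60.3% (1325 lower, 873 higher) after an offset for GC content and transcript length, which was added after the data were seen. The median absolute log2 fold change of the changed genes was 0.60, and 224 of them (26 higher, 198 lower) changed at least 1 log2 unit. The total was 641 without PD-L1 dish 1, 745 without PD-L1 dish 2, 3512 without PD-L1 dish 3 and 545 without Vector dish 1. The higher genes numbered 46, 69, 1271, 35, 119 and 109 when PD-L1 dishes 1 to 3 and then Vector dishes 1 to 3 were left out in turn. In all 6 of those fits, 453 of the changed genes were called, 19 of them higher and 434 lower.

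**Figure D2:**
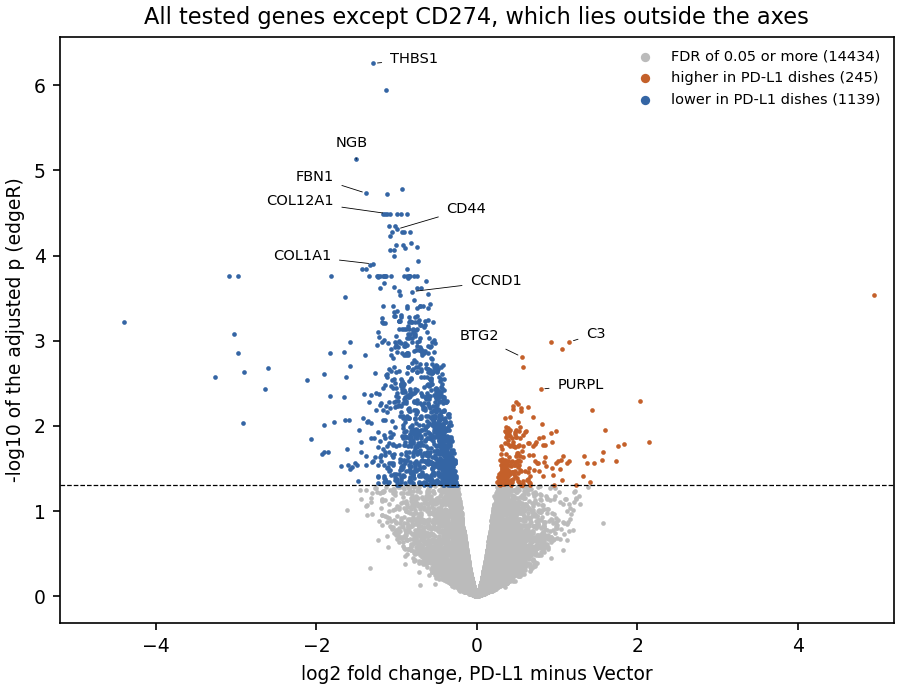
Each point is a tested gene, with its log2 fold change (PD-L1 minus Vector) on the x axis and -log10 of its edgeR adjusted p on the y axis; the dashed line marks an adjusted p of 0.05. The 1139 lower genes (blue) outnumber the 245 higher genes (orange, a number that includes CD274, which lies outside the axes).

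Collagen genes were lower as a group. In the list of fibrillar and basement-membrane collagens, 11 of 15 tested members fell, 0 rose, and the median log2 fold change was -0.998. COL4A1 fell from 189 ± 19.3 to 94.5 ± 7.01 CPM and COL12A1 by 1.12 ± 0.10 on the log2 scale, both with an adjusted p of 3.21e-05. COL1A2, the partner chain of COL1A1, fell from 325 ± 68.1 to 148 ± 9.44 CPM. Adjusted over the list alone, 13 members were lower. Without PD-L1 dish 3 the number of lower members was 8, and with the GC and length offset it was 9. The list passed the camera test with a preset correlation (adjusted p = 8.74e-11), but not with a correlation estimated from these dishes (adjusted p = 0.479 with an estimated correlation). The list medians relative to the Vector mean were -1.14, -1.03 and -0.89 in PD-L1 dishes 1 to 3. They were 0.29, -0.34 and 0.03 in Vector dishes 1 to 3, so the list also moved between control dishes.

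Mesenchymal genes moved in the same direction. Of 21 tested members, 13 fell and 0 rose, with a median log2 fold change of -0.70. MMP2, a gelatinase, was 2.34-fold lower, and the collagen-binding protein SPARC fell from 595 ± 124 to 328 ± 43.5 CPM. VIM, the intermediate filament vimentin, was 1.62-fold lower, at 391 CPM in Vector and 241 CPM in PD-L1 dishes. There were 14 lower members when adjusted over the list alone, 12 without PD-L1 dish 3 and 10 with the GC and length offset. The camera test gave an adjusted p of 8.95e-08 (adjusted p = 0.479 with an estimated correlation). Of the transcription factors in this list, SNAI2 fell by 0.47 on the log2 scale, an example chosen after its value was seen. TWIST1, TWIST2, SNAI1, ZEB1 and ZEB2 did not pass the test. In the epithelial list 0 of 14 members changed (0 adjusted over the list alone), and camera gave an adjusted p of 0.311. Its most abundant members KRT8 and DSP had log2 fold changes of -0.18 and 0.10, with adjusted p of 0.266 and 0.589. Without PD-L1 dish 3, however, 1 member was higher and 3 were lower, and KRT8 and DSP passed with adjusted p of 9.82e-04 and 0.0260.

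Genes that respond to transforming growth factor beta (TGF-β) were mostly lower, with 11 of 18 members down and 1, ID2, up (log2 fold change 0.30 ± 0.07). THBS1, described above, belongs to this list. ID1, an inhibitor of differentiation, was 1.73-fold lower, the matricellular CCN1 1.51-fold lower, and the ligand TGFB2 fell from 17.1 ± 0.64 to 10.4 ± 0.42 CPM. The list median was -0.56, and 13 members were lower and 1 higher when adjusted over the list alone. Camera gave an adjusted p of 6.96e-07 (adjusted p = 0.479 with an estimated correlation). In the actin cytoskeleton list 11 of 24 members fell and 0 rose. ACTN4 and ACTN1, the nonmuscle alpha-actinins, were 1.72-fold and 1.57-fold lower, TPM2, a tropomyosin, was 1.73-fold lower, and ACTB, beta-actin, fell from 4254 ± 262 to 2832 ± 307 CPM. The median was -0.36, 17 members were lower when adjusted over the list alone, and camera gave an adjusted p of 4.36e-07 (adjusted p = 0.479 with an estimated correlation). Without PD-L1 dish 3, 18 members were lower and 1 higher.

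Glioma subtype genes were lower for the mesenchymal subtype. In that list 11 of 16 members fell and 0 rose, with a median log2 fold change of -0.54. CD44, the hyaluronan receptor, fell from 417 ± 39.9 to 208 ± 23.0 CPM. SERPINA1, PLAUR (the urokinase receptor) and the annexin ANXA2 were 2.23-fold, 2.01-fold and 1.74-fold lower. Adjusted over the list alone, 13 were lower, and camera gave an adjusted p of 1.84e-08 (adjusted p = 0.479 with an estimated correlation). In the list of proneural and stem genes 5 of 13 members fell and 0 rose. Among them, the transcription factor SOX11 was 2.14-fold lower, the intermediate filament gene NES 1.56-fold lower, NCAM1 1.39-fold lower and SOX2 1.31-fold lower. Adjusted over the list alone, 5 were lower and 1 higher. That list did not pass the camera test (adjusted p = 0.135, median -0.07).

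Target genes of RAS-ERK signalling were also lower in part. Of 22 members 9 fell and 0 rose, with a median log2 fold change of -0.42. CCND1, the G1 cyclin D1, fell from 181 ± 11.8 to 103 ± 15.2 CPM. The receptor EPHA2, the MAP kinase phosphatase DUSP4 and the transcription factor ETV5 were 1.52-fold, 1.83-fold and 1.78-fold lower. Adjusted over the list alone, 12 were lower, and camera gave an adjusted p of 2.81e-04 (adjusted p = 0.479 with an estimated correlation). PD-L1 dish 1 had a list median of -0.59 relative to the Vector mean, against -0.30 and -0.27 in PD-L1 dishes 2 and 3. Of the 6 lists described so far whose camera test passed, each was still called with the preset correlation when any 1 dish was left out. With an estimated correlation camera gave these lists adjusted p of 0.426 to 0.593 in those fits.

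**Figure D3:**
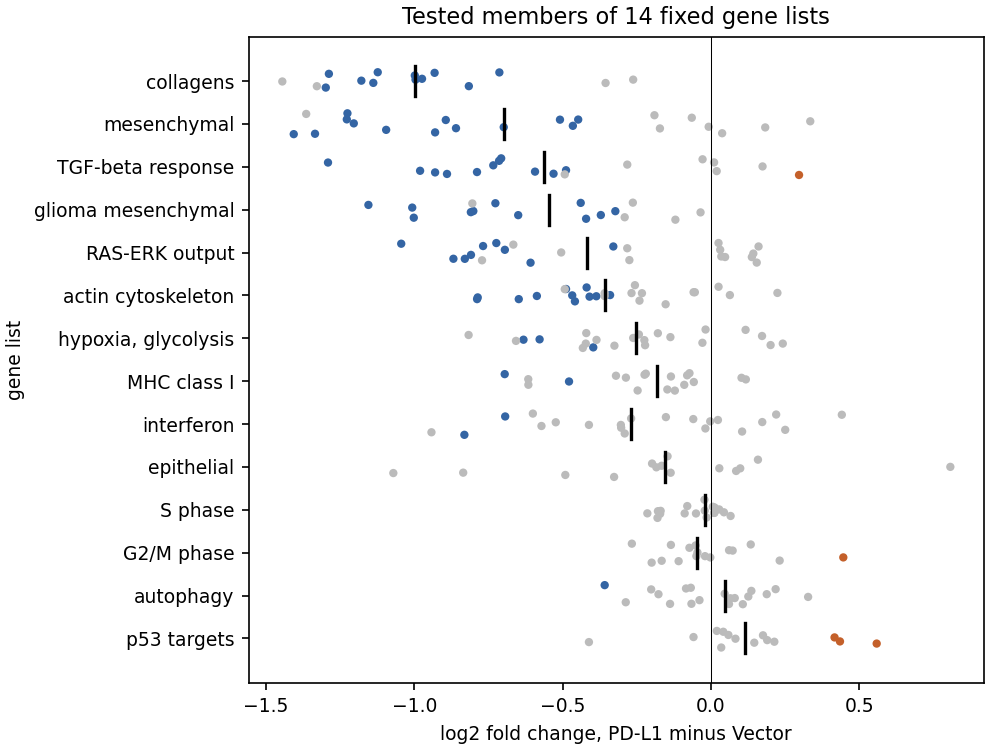
Log2 fold change (PD-L1 minus Vector, x axis) of every tested member of 14 gene lists fixed before the data were examined. Members with an edgeR adjusted p under 0.05 are blue (lower) or orange (higher), others grey, and the black bar is the list median, which runs from -0.998 for collagens to 0.11 for p53 targets.

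Of 18 genes of MHC class I presentation 2 fell and 0 rose. TAPBP, the peptide-loading factor tapasin, fell by 0.70 ± 0.11 on the log2 scale, and the peptidase ERAP2 by 0.48 ± 0.13. The list median was -0.18, with 5 lower when adjusted over the list alone and 7 without PD-L1 dish 3. The camera test gave an adjusted p of 0.00345 (adjusted p = 0.479 with an estimated correlation). Among 21 interferon-stimulated genes, OAS3 and IFI44 fell, being 1.78-fold and 1.62-fold lower. The same 2 genes passed in the count adjusted over the list alone, and 4 members were lower without PD-L1 dish 3. The list did not pass camera (adjusted p = 0.0686). Of 14 NF-κB and inflammatory genes, TNFAIP2 and the chemokine CXCL8 fell (log2 fold changes of -0.55 and -0.59, adjusted p of 0.00767 and 0.0484). There were 3 adjusted over the list alone, and camera gave an adjusted p of 0.0507. Leaving out PD-L1 dish 3 gave 5 lower members and a camera adjusted p of 0.0260 (adjusted p = 0.530 with an estimated correlation in that fit). Both lists passed camera after the GC and length offset, with adjusted p of 0.0399 and 0.0314 (adjusted p = 0.459 and 0.431 with an estimated correlation in that fit). Of 8 other checkpoint ligands and regulators, CD276 (B7-H3) was 1.25-fold lower. That list gave 2 lower genes adjusted over the list alone and an adjusted p of 0.135 in camera. Its count without PD-L1 dish 3 was 3 lower and 1 higher.

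The S-phase and G2/M lists did not pass the camera test. Of 18 S-phase genes 0 changed (0 adjusted over the list alone, camera adjusted p = 0.201, but 0.0356 on DESeq2 statistics; adjusted p = 0.479 with an estimated correlation on log2 CPM), and of 16 G2/M genes the kinesin-like CENPE alone changed, 1.36-fold higher (1 adjusted over the list alone, camera adjusted p = 0.644). Their medians were -0.02 and -0.05. Without PD-L1 dish 3, 4 S-phase genes were lower, and 2 G2/M genes were higher and 3 lower. Of 14 p53 target genes 3 rose and 0 fell: the antiproliferative gene BTG2, from 48.8 ± 2.48 to 71.9 ± 6.99 CPM, SESN1 by 1.33-fold, and MDM2, the ubiquitin ligase of p53, by 1.35-fold. The count adjusted over the list alone was 3 higher and 1 lower, and the count without PD-L1 dish 3 was 6 higher and 0 lower. Camera gave an adjusted p of 0.0507 for this list, and 0.0103 after the GC and length offset (adjusted p = 0.459 with an estimated correlation in that fit). CDKN1A, a further member, had a log2 fold change of 0.08 with an adjusted p of 0.529.

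Hypoxia and glycolysis genes had 3 of 22 members lower and 0 higher, namely the glucose transporter SLC2A1 (1.49-fold), the collagen prolyl hydroxylase P4HA1 (1.32-fold) and the carbonic anhydrase CA12 (1.55-fold). There were 6 lower when adjusted over the list alone and 5 without PD-L1 dish 3. Camera gave an adjusted p of 0.0173 (adjusted p = 0.630 with an estimated correlation). The camera call ended without PD-L1 dish 1, Vector dish 1 or Vector dish 3, with adjusted p of 0.124, 0.105 and 0.0621. LAMP1, a lysosomal membrane protein, was the only 1 of 19 autophagy genes to pass, 1.28-fold lower (1 adjusted over the list alone, 3 lower without PD-L1 dish 3). That list had a median of 0.05, a mean of -0.0035 and a camera adjusted p of 0.894. In the cholesterol synthesis list 1 of 21 genes was lower and 0 higher. Adjusted over the list alone 3 were higher and 1 lower, and the counts without PD-L1 dish 3 were also 3 higher and 1 lower. The median was -0.0006, the mean 0.03 and the camera adjusted p 0.583. Of 20 genes of the endoplasmic reticulum stress and amino acid response 0 changed (0 adjusted over the list alone, camera adjusted p = 0.536), but 2 were higher and 3 lower without PD-L1 dish 3.

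Quality-related lists were examined in the same way. The 13 mitochondrially encoded transcripts had a median log2 fold change of -0.13, with 0 members called singly or adjusted over the list alone, and 4 lower without PD-L1 dish 3. Their camera adjusted p was 0.0499 (adjusted p = 0.571 with an estimated correlation), and the call ended with upper-quartile scaling (0.0548) and without PD-L1 dish 2 or 3 or Vector dish 2 or 3 (0.0880 to 0.258). After the GC and length offset 7 of the 13 transcripts were lower, with a median of -0.22 and a camera adjusted p of 9.02e-05 (adjusted p = 0.431 with an estimated correlation in that fit). Genes whose symbol begins with MT-, a set not limited to these 13, took 2.71, 2.51 and 2.46% of counts in PD-L1 dishes 1 to 3. They took 2.63, 2.84 and 2.97% in Vector dishes 1 to 3. Cytosolic ribosomal protein genes (0 of 33 changed, 0 adjusted over the list alone) had a camera adjusted p of 0.311, and a median of 0.29 in PD-L1 dish 3 relative to the Vector mean, against -0.03 and -0.08 in PD-L1 dishes 1 and 2. This list was lower with an adjusted p of 0.0328 without PD-L1 dish 3 (7 members lower) and higher with 0.00909 without PD-L1 dish 2. Neither call was kept (adjusted p = 0.768 and 0.693 with an estimated correlation in those fits). Nuclear genes of oxidative phosphorylation (0 of 27, 0 adjusted over the list alone; 3 lower without PD-L1 dish 3) had an adjusted p of 0.311. Of 13 heat-shock and stress genes, HSPB1 and DNAJB1 fell, being 1.52-fold and 1.29-fold lower (2 adjusted over the list alone, camera adjusted p = 0.135). Without PD-L1 dish 3, 4 members were lower and camera gave an adjusted p of 0.0386 (adjusted p = 0.530 with an estimated correlation in that fit).

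Markers of other cell types ranged from absent to abundant, with the astrocyte enzyme GLUL at 503.6 ± 14.5 CPM in PD-L1 and 464.6 ± 10.1 CPM in Vector dishes (adjusted p = 0.350). In the astrocyte list 3 of 6 tested members fell, with 3 adjusted over the list alone and a camera adjusted p of 0.135. GFAP, the astrocyte filament protein, was at 1.70 ± 0.22 CPM in PD-L1 and 3.18 ± 0.56 CPM in Vector dishes, GJA1 was 1.22-fold lower and FABP7 1.99-fold lower. FABP7 lost its call when PD-L1 dish 1, 2 or 3 was left out (adjusted p of 0.211 to 0.250). In the neuronal list 1 of 7 tested members fell, MAP2 (1.45-fold), with 2 adjusted over the list alone and a camera adjusted p of 0.135. Lists with under 5 tested members were described only. MBP, an oligodendrocyte gene, was at 5.30 ± 0.40 against 7.98 ± 0.92 CPM. Of leukocyte markers, AIF1 was at 0.09 ± 0.10 against 0.72 ± 0.14 CPM (4, 1 and 0 counts against 14, 18 and 12), while PTPRC had 5 to 11 counts per dish and CD3E 0 to 3. Of endothelial markers, the receptor gene TEK was at 0.25 ± 0.09 against 2.03 ± 0.32 CPM, KDR was 2.20-fold lower and CDH5 was at 2.11 ± 0.40 against 1.30 ± 0.53 CPM (adjusted p = 0.151).

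The dishes of a group were not alike. PD-L1 dish 3 stood apart from PD-L1 dishes 1 and 2. On the first principal component, which held 50.8% of the variance, the PD-L1 dishes scored 27.97, 26.2 and 7.99, and the Vector dishes -30.8, -15.0 and -16.4. Expression followed the GC content of genes differently in each dish. Across genes, which are not independent replicates, Spearman's rho between GC content and a dish's deviation from the mean of the 6 dishes was -0.42, -0.28 and 0.21 in PD-L1 dishes 1 to 3. It was 0.41, 0.01 and 0.14 in Vector dishes 1 to 3. With transcript length in place of GC content, rho was 0.08, 0.20 and -0.41 in PD-L1 dishes 1 to 3. In Vector dishes 1 to 3 the rho with length was 0.01, -0.13 and 0.18. PD-L1 dish 3 thus had a stronger trend with length than with GC content. The log2 fold change correlated with GC content across genes with a rho of -0.29. With the GC and length offset, 2198 genes were called, of which 1235 were among the 1384. Of the 75 called genes named by the fixed rule besides CD274, 44 were called whichever dish was left out. The 31 others, each losing its call in at least 1 of those fits, included TP53INP1, FOXN4, L3MBTL1, LINC00649, ATF7IP2, GABRE, 1 gene without a symbol, PLXNA4, BGN, APCDD1L, IFI44, ERAP2, TNFAIP2, CXCL8, CD276, CENPE, SESN1, MDM2, SLC2A1, P4HA1, CA12, NCAM1, SOX2, GFAP, GJA1, FABP7, MAP2, MBP, KDR and DNAJB1. With the offset SLC2A1, P4HA1, CA12 and FABP7 did not pass (adjusted p of 0.0537, 0.0743, 0.154 and 0.136), and the 2 unnamed IDs given above had no GC value. Among the list genes named above, VIM, SPARC, KRT8, CCND1, ACTN4, CD44, NCAM1, SESN1, MDM2, SLC2A1, P4HA1, GFAP, MBP, DNAJB1, ID2, TWIST1, ZEB1, ZEB2 and CDKN1A overlap a gene on the opposite strand in GENCODE 29, so their counts are uncertain in the same way.

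**Figure D4:**
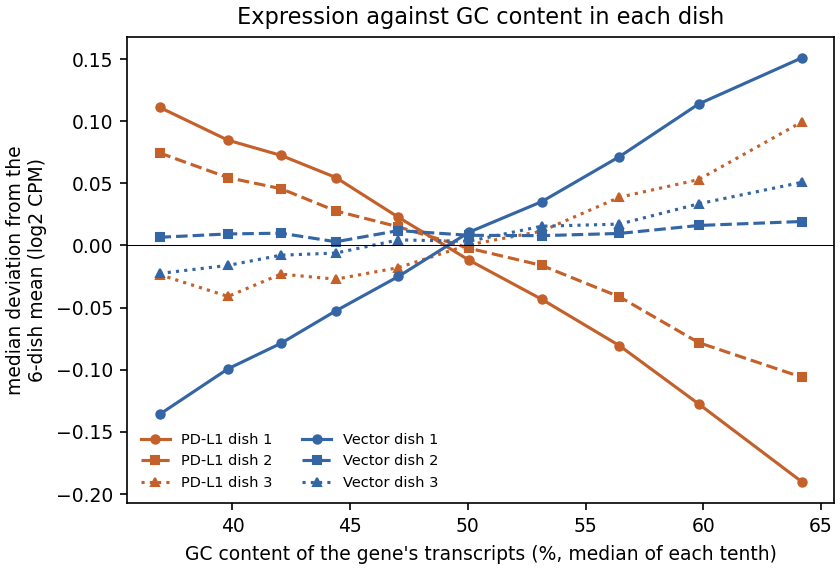
Median deviation of expression from the mean of the 6 dishes (log2 CPM, y axis) for genes in 10 equal bins of transcript GC content (percent, x axis), by dish. PD-L1 dishes 1 and 2 (orange circles and squares) fall with GC content, whereas PD-L1 dish 3 (orange triangles) and Vector dishes 1 and 3 (blue circles and triangles) rise.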

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

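The GC and length settings and the estimated correlation in fits that leave out 1 dish were chosen after the data were seen; the other settings were fixed before. CD274 stayed higher with a log2 fold change of 8.82 to 9.44 under every setting tried. The number of changed genes stayed within 1.5 times of 1384 under the 3 other scalings, DESeq2 (1380), limma-voom (1367), limma-trend (1357), no filter (1904) and the minimum of 5 CPM (1050). Upper-quartile scaling moved the higher genes from 245 to 379. The number fell to 530 at an FDR of 0.01, 224 at 1 log2 unit and 443 with glmTreat, by the construction of those thresholds. Leaving out 1 dish gave 545 to 3512 changed, 35 to 1271 higher and 510 to 2241 lower genes; the extremes were Vector dish 1 and PD-L1 dish 3, and the cause was not tested. With the GC and length offset 2198 genes changed, 873 of them higher. Without PD-L1 dish 3 as well, 3490 changed, 1600 higher and 1890 lower, and 14 lists were called. Deviations of same-numbered dishes correlated at -0.21, -0.05 and -0.19. The largest correlations with other numbers were 0.13, 0.14 and 0.23, and the smallest were 0.10, -0.08 and -0.06. The labels do not say what the replicate numbers share, so these values do not decide whether the dishes were paired. With the replicate block 1447 genes changed (238 higher, 1209 lower) and 8 lists were called, mitochondrial transcripts losing their call. With the block and the GC and length offset, 369 higher genes were called in a total of 1317. The 9 called lists numbered 17 with DESeq2 (cameraPR, the cause not tested), which added the interferon, NF-κB, checkpoint, S-phase, p53, proneural, astrocyte and heat-shock lists. They numbered 4 with fry and 0 with an estimated correlation, where the smallest adjusted p was 0.479. Upper-quartile scaling and limma-voom each added NF-κB and p53. Limma-trend and no filter each added interferon and NF-κB, and the minimum of 5 CPM added p53. In limma's fry test the collagen, TGF-β and glioma mesenchymal lists were called too, and p53 targets were added. Fry tests a list against no change and camera tests it against the other genes, so their counts are not like for like. The estimated correlation was 0.77 for collagens. Leaving out single dishes added, in 1 or more fits, the interferon, NF-κB, p53, proneural, ribosomal, oxidative phosphorylation and heat-shock lists, none of them with an estimated correlation. Lists that did not pass in the main test turned direction in places. Autophagy did with upper-quartile scaling, the block, the GC and length offset alone, without PD-L1 dish 3 and with the block, and without PD-L1 dish 1 (adjusted p of 0.985, 0.986, 0.757, 0.880, 0.712 and 0.973). So did G2/M without Vector dish 2 (0.991; range over the left-out dishes 0.412 to 0.991), cholesterol without Vector dish 1 (0.733; 0.310 to 0.838) and the endoplasmic reticulum stress list without PD-L1 dish 3 (0.827; 0.232 to 0.827). Ribosomal proteins did without PD-L1 dish 3 or Vector dish 3 (0.0328 and 0.992, range 0.00909 to 0.992), and oxidative phosphorylation without PD-L1 dish 3 (0.871; 0.0443 to 0.871). Ribosomal proteins and oxidative phosphorylation did so with the offset without PD-L1 dish 3 (0.00773 and 0.516). Genes not called in the main test had log2 fold changes of the other sign as follows. MCM4 had 0.0103 with upper-quartile scaling, 0.0063 without PD-L1 dish 3 (range over left-out dishes -0.0505 to 0.0063), and 0.0105, 0.0256 and 0.0111 with the offset alone, without that dish and with the block. RPL8 had 0.0383 and 0.0441 without PD-L1 dish 1 or 2 (range -0.2016 to 0.0441), and 0.0375 and 0.0359 with the offset alone and with the block. COX7C had -0.0362, -0.1187 and -0.0388 in the 3 offset fits. RPS2 had -0.1584 and -0.0375 without PD-L1 dish 3 or Vector dish 3 (range -0.1584 to 0.1206), and -0.0508 with the offset without PD-L1 dish 3. ATP5F1B had -0.0044 with no filter and -0.0277 to -0.0036 without PD-L1 dish 3, Vector dish 1 or Vector dish 3 (range -0.0277 to 0.0499). The cause was not tested for any of these. Depth limits genes near 3 counts (0.135 to 0.191 CPM), such as AIF1.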

Other observations

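The tests in this part (gene families, noncoding share, other splits of the dishes, scaling, position of PD-L1 dish 3, GC and length offset, cycling genes and number of lines) were chosen after the results were seen. Beyond the fixed lists, genes were grouped by the root of their symbol, which gave 200 families of at least 10 tested members. With camera's preset correlation 9 families passed, 7 lower and 2 higher, and 0 passed with an estimated correlation (adjusted p = 0.982 for each). Keratins (KRT) fell in 9 of 23 members with 0 higher, a median log2 fold change of -0.71. KRT80 fell from 60.7 to 33.6 CPM; several other keratins, such as KRT14, have near-identical copies. The genes given here were picked after their values were seen. Cadherins (CDH) fell in 6 of 15 members, CDH13 by 1.09 ± 0.10 on the log2 scale, and integrin alpha chains (ITGA) in 5 of 11, ITGA3 by 1.07 ± 0.16 and ITGA6 by 0.83 ± 0.08. Interleukins and their receptors (IL) fell in 7 of 33, among them IL13RA2, a receptor studied as a glioma antigen, by 1.07 ± 0.16 and IL11 by 0.94 ± 0.16. Zinc finger genes (ZNF) went the other way, with 16 higher and 9 lower of 479 and a median of 0.10, but passed only without the GC and length offset (adjusted p of 0.0445 and 0.0852). The other higher family, golgins (GOLGA), had 3 higher and 1 lower of 15 and passed without and with the offset (0.0366 and 0.0329), but its 3 higher members are copies or a pseudogene whose reads are uncertain. Among genes with a biotype in GENCODE 29, noncoding genes made up 38 of 236 higher calls (16.1%), 37 of 1122 lower calls (3.30%) and 12.8% of tested genes (Fisher's exact p = 8.85e-12 for higher against lower). With the offset they made up 8.71% of higher and 3.92% of lower calls (Fisher's exact p = 4.13e-06), both below the share of tested genes, and without PD-L1 dish 3 they made up 11.2 and 2.84%, against 13.98% of tested genes (Fisher's exact p = 2.49e-22).

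The weakly expressed genes given next were picked after their values were seen. HCAR2, a hydroxycarboxylic acid receptor, had 24, 19 and 24 counts in PD-L1 dishes 1 to 3 and 0, 2 and 0 in the Vector dishes. HCAR2, KLHL1, CDH13 and ITGA6 overlap a gene on the opposite strand in GENCODE 29 and are uncertain for that reason. KLHL1 had 1, 1 and 0 against 18, 20 and 16 counts, SCT 14, 4 and 3 against 68, 56 and 74, and CD4 7, 4 and 1 against 33, 23 and 26. In other genes PD-L1 dish 3 was at the Vector level: NTMT2 had 1, 2 and 10 against 14, 11 and 9 counts, and SMIM24 1, 2 and 11 against 12, 11 and 6. Genes were then called from the other 5 dishes, and PD-L1 dish 3 was placed between the Vector mean (0) and the mean of PD-L1 dishes 1 and 2 (1). For the 20 genes lower by at least 2 log2 units dish 3 lay at a median of 0.91 (95% bootstrap interval 0.72 to 1.07). It lay at 0.68 for genes lower by 1 to 2 units and for those lower by 0.5 to 1, and at 0.35 (0.31 to 0.40) for the 1197 genes lower by under 0.5. For higher genes it lay at 0.17 under 0.5, 0.32 from 0.5 to 1 (259 genes), 0.36 from 1 to 2 (70 genes, 0.28 to 0.52) and 0.82 at 2 or more (4 genes, 0.38 to 1.10, CD274, at 0.926, not among them). Size of change went with expression: the median was 0.60 CPM for the 20 genes and 70.3 CPM for the 1197. No other dish was placed by size of change, so the rise with size cannot be called particular to dish 3.

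Lower calls outnumbered higher calls. Removing CD274 before scaling left 1383 changed genes with 82.4% lower. CD274 held at most 0.14% of the counts of a dish, so its removal could move the scaling little and does not decide the question. The lowest share of lower calls over the 3 other scalings was 72.81%, so no scaling tried removed the excess. A scaling error common to all of them was not tested. The share was 60.28% after the GC and length offset (95% interval 58.2 to 62.3, over genes only), with more lower and more higher calls than before, 54.2% with the offset and without PD-L1 dish 3, and 72.0% with the offset and the replicate block, so that trend as the whole cause stays open. Other splits of the dishes into 3 and 3 bear on all calls. The real split was the 1 of 10 that gave 1384 changed genes, and the highest other gave 0 in edgeR. Every other split mixes PD-L1 and Vector dishes on each side, so a group difference adds to its spread and holds its calls down. That 0 is therefore no support for the calls, and 10 splits are too few for a share under 0.05. 

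PD-L1 dish 3 lay between the groups. Over 2937 genes called without it and above 5 CPM, its median position was 0.4063 (95% interval 0.385 to 0.423). The other 5 dishes, placed in the same way, lay at 0.648 (Vector dish 2) to 1.41 (Vector dish 1). RNA of vector cells mixed into the dish would place CD274 there too, but CD274 lay at 0.926. After the GC and length offset the median position of dish 3 was 0.5778 (0.559 to 0.596, over genes only). The other 5 dishes then lay at 0.761 (Vector dish 2) to 1.23 (Vector dish 1), so the offset did not bring dish 3 into their range. Each dish was placed by its own genes, 2908 for dish 3 and 1522 for Vector dish 2. The calling itself can also pull a left-out dish under 1. GC and length trends as the whole cause therefore stay open. The offset corrects every dish, so the shift cannot be placed in single dishes. Cell density and time of harvest were not tested.

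Collagen, mesenchymal, TGF-β, actin, glioma mesenchymal and RAS-ERK genes were lower together. After the GC and length offset the median of their 113 members was -0.4743 (95% bootstrap interval -0.66 to -0.30), against -0.51 before. The offset thus moved the median little, which argues against that trend as the whole cause. A different share of cycling cells is argued against by a median of -0.0339 (-0.08 to 0.0039) over 34 S and G2/M genes. Both intervals are over genes only and treat genes as independent. The lists were pooled because they were lower in these same dishes. The labels describe 1 transduced line per group, so an effect of PD-L1 and a difference between lines that arose during transduction or selection cannot be told apart. Cell density at harvest, to which matrix and adhesion genes may respond, also stays open and was not tested.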
